A study of Homo sapiens with 6 samples.

How the data were processed

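The samples were 6 RNA-seq libraries of MUM2B cells, 3 with an empty vector and 3 overexpressing LACTB. Per the labels' protocols, the cells were grown in RPMI medium with serum, RNA was extracted with Trizol, libraries were made from total RNA with a NEBNext Ultra RNA kit, and a NovaSeq gave paired-end reads of 150 bp. Per the submitters' processing notes, HISAT2 2.0.5, featureCounts 1.5.0-p3, DESeq2 1.16.1 and the human build GRCh38 (hg38) were used, with neither role nor order given; read trimming, the treatment of reads that match several places, the use of strand and the annotation release are not given in the sources used here. Reads from a gene and an antisense or overlapping neighbour, or from near-identical copies, therefore cannot be told apart with certainty. The groups and replicate numbers came from the labels.

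The authors deposited 1 file per library, with a gene symbol, an Ensembl gene ID and an FPKM value (fragments per kilobase of exon, scaled to library size) for 58735 genes. All 58735 gene IDs matched GENCODE 29 (Ensembl 94, GRCh38), and 58708 symbols were equal to those in that annotation, from which coordinates, gene types, exon lengths and GC content were taken. Each FPKM value times the exon length of its gene was a whole multiple of 1 step per library for 100% of the values above 0 (tolerance 0.1 reads), so the number of reads behind each value and the depth of each library could be recovered: 16978799 to 18395631 reads in genes. The authors' effective library size differed from that total by a factor of 0.983 to 1.02. In the FPKM values, therefore, the effect of library size and of exon length was already divided out by the authors. 28106 genes were listed at 0 in all libraries.

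Differential expression was computed with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend) on log2(FPKM + 1), for the 11875 genes with a mean of at least 1 FPKM over the 6 libraries. A gene rose or fell when its Benjamini-Hochberg adjusted p was under 0.05. Fold changes are differences of log2(FPKM + 1), which understate the change of genes with low values; where a change is given as a number of times, it is the ratio of the group means of FPKM. FPKM is not a count, so no count model was used for the main result, and limma voom on the recovered reads was an alternative.

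Gene lists were tested with limma camera on the moderated statistics with a preset correlation of 0.01, for the 24 of 27 lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other tested genes. Camera with an estimated correlation and fry, which does not compare a list with other genes, were alternatives. The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined, except where stated. The rule named LACTB, YAP1, WWTR1 and PPP1CA; the 12 genes with the largest rise and the 12 with the largest fall among those with adjusted p under 0.05, a mean of at least 2 FPKM and no overlap between the groups; and up to 2 risen and 2 fallen members of each list with the smallest p. Of the members so named, STK3, ACSS2, LEF1, SP5, HSPA1A, HSPA1B and BAG3 lost their call when single libraries were left out and are given with the alternatives only. Some genes that the rule names are not reported here.

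The alternatives were a pseudocount of 0.1, no filter, a mean of at least 5 FPKM, TPM, median-of-ratios scaling, quantile normalization, eBayes without trend or with robust estimation, library weights, a replicate block, protein-coding genes only, a stricter threshold and each library left out in turn. The removal of trends in GC content and exon length, and voom for single genes and lists, were added after seeing the data. Replicates were compared first: a chi-square test of the recovered reads gave 2.02 to 12.4 per degree of freedom between libraries of one group, so no pair agreed within sampling noise, and each library counted as 1 sample. Empty vector replicate 3 differed most from the others of its group.

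The gene and list tests were tested on simulated data for the comparison of LACTB with empty vector, with counts drawn at the real means and library sizes. Among 11899 tested genes, 46.9% of the genes changed 1.25-fold were called, 85.7% at 1.5-fold, 93.8% at 2-fold and 100% at 4-fold, with 17 of 11678 unchanged genes called. Correct calls numbered 23, 42, 45 and 45 at these folds. The 17 false calls were therefore a larger share of all calls than the 0.05 that the threshold aims at. A shifted list of 30 genes was called, and 0 of 100 random lists were. Genes were drawn independently of each other with 1 common dispersion (0.00179). False list calls from correlated genes, and extra spread of single genes or libraries, were therefore not tested. Apart from the shifted list, only 45 to 49 tested genes per fold were changed, against 3796 genes called in the real data. The adjusted threshold was thus stricter in the simulation, and the shares called do not carry over to the real test. Tables were read with pandas 2.3.3 in Python 3.11.15, and figures were drawn with matplotlib 3.10.9.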

Results

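RNA sequencing compared MUM2B cells, which the labels give as human melanoma cells, that stably carried either an empty vector or a vector overexpressing LACTB. LACTB is a serine beta-lactamase-like protein of the mitochondrial intermembrane space that has been described as a tumour suppressor, and the study relates it to the Hippo pathway effector YAP and the protein phosphatase catalytic subunit PPP1CA. Each group held 3 libraries, and the comparison asks which genes differ between cells with raised LACTB and cells with the empty vector. The identity of the line rests on the labels and was not tested; 20 of 22 melanocyte markers lay under 1 FPKM. The libraries held 17892101, 18395631 and 17828472 reads in genes for empty vector replicates 1 to 3, and 17821609, 16978799 and 17644157 for LACTB replicates 1 to 3. At these depths, 3 reads in a gene with 2 kb of exon sequence were worth 0.0827 to 0.0872 FPKM. Pearson's r of the log2 values across the 11875 tested genes, which are not independent replicates, was 0.989 to 0.992 between libraries of one group and 0.974 to 0.977 between groups. The first principal component held 58.6% of the variance and separated the groups. Mitochondrially encoded genes took 3.61% of the reads in empty vector replicate 3, against 5.54% and 5.62% in the other empty vector libraries and 4.65% to 5.04% in the LACTB libraries. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these libraries, which can be technical.

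LACTB (ENSG00000103642; GRCh38 chromosome 15, 63121800 to 63142061) rose 42.4-fold in the cells carrying it. Its level was 3.97 ± 0.675 FPKM with empty vector and 168.2 ± 6.285 FPKM with LACTB (SD, n = 3 each). The empty vector libraries lay at 3.81, 3.385 and 4.71 FPKM from 244 to 337 reads each, and the LACTB libraries at 173.9, 169.3 and 161.5 FPKM from 11537 to 12509 reads each, so all 6 libraries matched their labels. The log2 fold change was 5.10 (SE 0.093; limma, adjusted p = 7e-07). Reads of the cell's own gene and of the introduced copy are counted together in this value.

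Beyond LACTB, a large part of the expressed genes differed between the groups, mostly by small amounts. Of 11875 tested genes, 1758 rose (14.8%) and 2038 fell (17.2%) in LACTB cells; as TPM, with 16070 genes tested, rises outnumbered falls, at 1615 against 1295. The median absolute log2 fold change of the genes that changed was 0.31. On the log2(FPKM + 1) scale, 88 rose and 48 fell with a log2 fold change of at least 1 in size. These counts leave out some genes whose ratio of mean FPKM exceeds 2, such as BAMBI (3.51-fold, log2 fold change 0.88). Among 10120 tested protein-coding genes, 1587 rose and 1908 fell. The test was limma on log2(FPKM + 1) with Benjamini-Hochberg adjustment, and 5029 genes had an unadjusted p under 0.05. Without LACTB replicate 2 the number of genes that rose was 1115, and at an adjusted p under 0.01, 847 rose and 1004 fell.

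**Figure D1:**
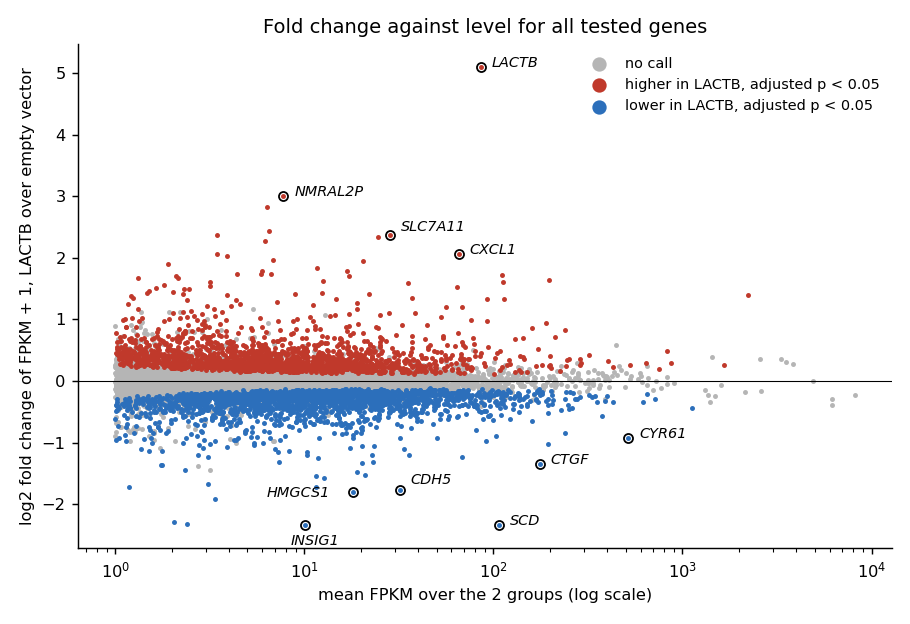
Mean FPKM over both groups (log axis) against the log2 fold change of FPKM + 1 for each of the 11875 tested genes, 1 point per gene. Red points rose (1758 genes), blue points fell (2038 genes) and grey points passed no threshold; LACTB stands alone at 5.10.

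On the log2(FPKM + 1) scale, and among genes with a mean of at least 2 FPKM, the largest rises after LACTB itself were those of NMRAL2P, a transcribed pseudogene that went from 0.959 ± 0.303 to 14.6 ± 0.286 FPKM, and the pseudogene AC245100.3, which went from 0.924 ± 0.948 to 11.7 ± 2.24 FPKM on 14 and 177 reads summed over each group. SERPINB2, the plasminogen activator inhibitor type 2, rose 8.70-fold to 11.7 ± 0.954 FPKM. AKR1C1, an aldo-keto reductase of steroid and xenobiotic metabolism, rose 14.75-fold from 0.439 ± 0.0425 to 6.48 ± 0.152 FPKM, more than AC245100.3 (12.65-fold) by the ratio of mean FPKM, and SLC7A11, the cystine importer, rose 5.66-fold from 8.47 ± 0.697 to 48.0 ± 2.05 FPKM. The neutrophil-attracting chemokines CXCL8 and CXCL1 rose 5.58-fold and 4.32-fold, to 41.4 ± 2.20 and 106.3 ± 2.80 FPKM. The secreted peptide gene ADM2 rose 7.42-fold, the Toll-like receptor 4 partner LY96 8.79-fold, the cytokine receptor subunit IL20RB 7.38-fold and IGFN1 5.19-fold. The value of LY96 rests on few reads: it went from 0.71 ± 0.30 to 6.22 ± 1.67 FPKM on 23 and 201 reads summed over each group. Limma's adjusted p for these 11 genes lay between 2.59e-06 (AKR1C1) and 0.000898 (AC245100.3), and in each gene, as the rule for naming it requires, all 3 LACTB libraries lay above all 3 empty vector libraries. AKR1C1, CXCL1, NMRAL2P and AC245100.3 have close copies in the genome, so their reads can be shared with those copies.

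On the log2(FPKM + 1) scale the largest falls by the same rule were those of the lipid genes INSIG1 and SCD, whereas WNT7A and FGFBP1 fell more by the ratio of mean FPKM. INSIG1, which retains the sterol-regulated transcription factors in the endoplasmic reticulum, went from 17.45 ± 0.620 to 2.65 ± 0.272 FPKM, 6.58-fold lower, with a log2 fold change of -2.34 (SE 0.064; limma, adjusted p = 2.93e-06). The desaturase gene SCD went from 179.5 ± 5.48 to 34.85 ± 0.725 FPKM, 5.15-fold lower. HMGCS1 and DHCR7, enzymes of cholesterol synthesis, were 3.79-fold and 3.26-fold lower. WNT7A, a Wnt ligand, went from 4.68 ± 0.374 to 0.136 ± 0.0236 FPKM, 34.5-fold lower (log2 fold change -2.32), on 1150 and 33 reads summed over each group. FGFBP1, a carrier of fibroblast growth factors, had 296 reads over the 3 empty vector libraries and 3 reads over the LACTB libraries, all in LACTB replicate 1, a log2 fold change of -2.28. Its ratio of mean FPKM was 99.7, with an exact (Clopper-Pearson) 95% interval of 33.8 to 486.4 that covers counting error only. CDH5, the vascular endothelial cadherin, went from 49.8 ± 2.56 to 14.0 ± 0.453 FPKM. The NAD synthesis gene QPRT was 3.75-fold lower, the sphingosine-1-phosphate exporter SPNS2 5.45-fold and the transcriptional co-regulator CITED4 3.30-fold. Limma's adjusted p was at most 0.000524 for these 10 genes. The microRNA gene MIR125B1 was also among the 12 largest falls, at 26 against 6 summed reads (limma, adjusted p = 0.0443), and its call was lost when any 1 of 5 libraries was left out (adjusted p = 0.0814 without empty vector replicate 1 or 2, 0.111 without empty vector replicate 3, 0.13 without LACTB replicate 2 and 0.131 without LACTB replicate 3; 0.000873 to 0.159 over all its alternatives). The call was also lost with a pseudocount of 0.1, without a filter, as TPM, without the variance trend and with robust estimation, among others.

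**Figure D2:**
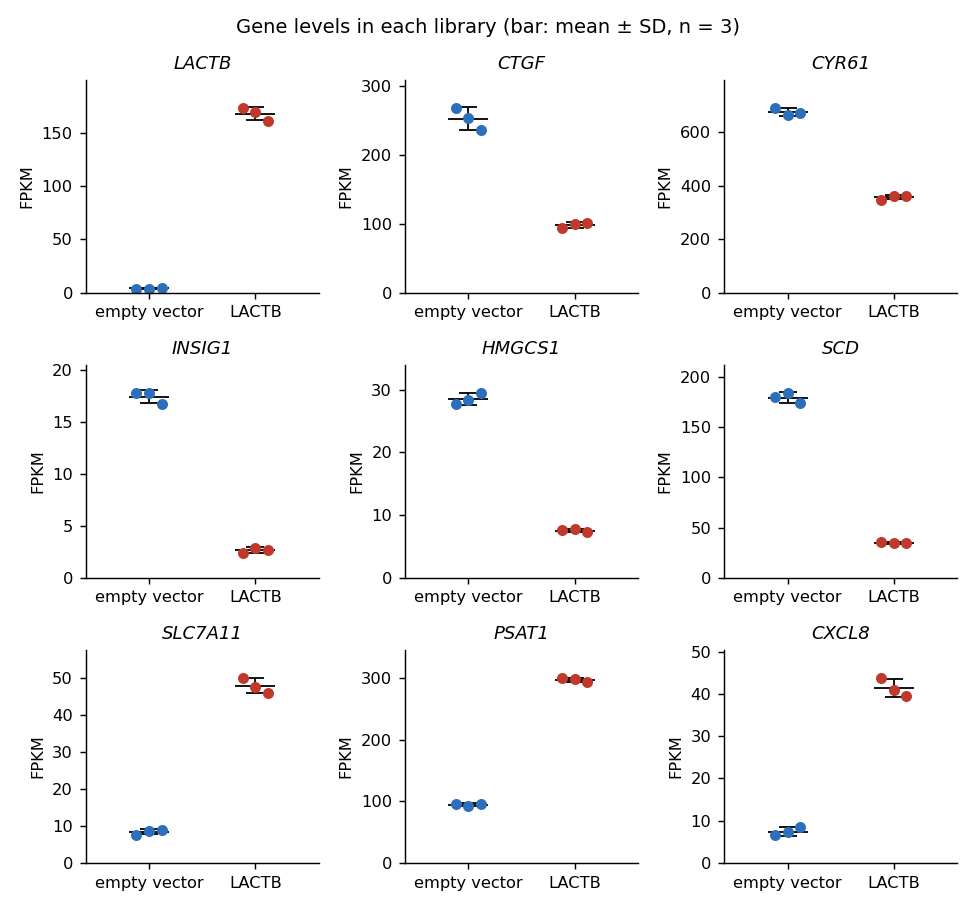
FPKM of 9 genes in each of the 6 libraries, on linear axes from 0; points are libraries, the wide bar is the group mean and the whiskers are ± SD (n = 3). LACTB, SLC7A11, PSAT1 and CXCL8 lie higher in the 3 LACTB libraries, and CTGF, CYR61, INSIG1, HMGCS1 and SCD lower, with no overlap between the groups.

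YAP1 itself, the transcriptional co-activator that the Hippo kinases restrain, passed no threshold. It stood at 29.01 ± 1.06 FPKM with empty vector and 32.0 ± 1.25 FPKM with LACTB (log2 fold change 0.14, SE 0.046; limma, adjusted p = 0.0632), with all 3 LACTB libraries above the others. Its adjusted p was 0.03 after quantile normalization, and 0.0382 with voom on recovered reads or 0.0175 after removal of GC and length trends, both added after seeing the data, and ran from 0.0175 to 0.178 over its 18 alternatives. WWTR1, the YAP paralogue also known as TAZ, fell from 14.6 ± 0.178 to 10.8 ± 0.429 FPKM (log2 fold change -0.41; limma, adjusted p = 0.000711). PPP1CA stood at 52.5 ± 3.52 and 51.2 ± 1.20 FPKM (log2 fold change -0.035; limma, adjusted p = 0.669), while another catalytic subunit of the same phosphatase, PPP1CB, fell from 27.7 ± 1.13 to 21.1 ± 0.292 FPKM. These values are RNA levels, so they leave open the amount, phosphorylation and activity of the proteins. Among 27 tested Hippo pathway components, 3 rose and 4 fell (1 and 4 when adjusted over the list alone), MAP4K4 among those that rose (1.23-fold), and the list as a whole passed no threshold (median log2 fold change -0.007; limma camera, adjusted p = 0.925).

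Targets of YAP and TAZ with their TEAD partners went both ways. CTGF and CYR61, secreted matrix proteins that are widely used as readouts of YAP, fell from 252.5 ± 16.6 to 98.2 ± 3.75 FPKM and from 676.3 ± 14.5 to 358 ± 8.64 FPKM, log2 fold changes of -1.35 and -0.92 (limma, adjusted p = 1.27e-05 and 2.31e-05). F3, the coagulation tissue factor, and GADD45A, a growth arrest gene, rose 1.39-fold and 1.37-fold to 61.1 ± 0.702 and 78.0 ± 2.77 FPKM. The largest rise among the tested targets was that of ANKRD1, named after its values were seen. It went from 9.04 ± 0.601 to 13.9 ± 1.29 FPKM, 1.54-fold (limma, adjusted p = 0.00165). Of 20 tested targets, 6 rose, 8 fell and 6 passed no threshold (6 rose and 10 fell when adjusted over the list alone), with a median log2 fold change of -0.12. Against other genes the list passed no threshold (limma camera, adjusted p = 0.204, and 0.501 with an estimated correlation). The limma rotation test fry, which asks only whether the members move on balance one way, gave an adjusted p of 0.00174 toward lower, the lowest of the 20 alternatives for this list; the highest was 0.501.

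Genes of cholesterol synthesis fell almost as a block. Of 23 tested members of the sterol synthesis list, 22 fell and none rose (22 also when adjusted over the list alone), with a median log2 fold change of -1.09. Besides INSIG1 and HMGCS1, chosen by rule, SREBF2, the transcription factor of the pathway and named after its values were seen, fell from 27.9 ± 2.07 to 16.8 ± 0.734 FPKM. The remaining member, TM7SF2, stood at 1.07 and 1.01 FPKM. Fatty acid synthesis genes fell as well: 13 of 18 tested members fell and 2 rose (14 and 2 when adjusted over the list alone), with a median log2 fold change of -0.35. After SCD the smallest p belonged to the phosphatidate phosphatase gene LPIN1, which was 2.10-fold lower, while the malic enzyme ME1 rose 1.45-fold. Limma camera gave adjusted p = 5.66e-19 for the sterol list and 7.42e-07 for the fatty acid list.

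Genes of the amino acid response and of the unfolded protein response made up the list with the highest median. Of 26 tested members, 22 rose and 3 fell (22 and 3 when adjusted over the list alone), with a median log2 fold change of 1.00. PSAT1, an enzyme of serine synthesis, rose from 94.85 ± 2.28 to 297.8 ± 3.44 FPKM, and SLC7A11 is also in this list. ATF4, the transcription factor at the centre of the amino acid response and named after its values were seen, rose from 159.4 ± 3.90 to 263.5 ± 8.57 FPKM. The 3 members that fell, PDIA4, SDF2L1 and HYOU1, encode folding factors of the endoplasmic reticulum; PDIA4 went from 48.7 ± 2.15 to 35.3 ± 0.854 FPKM and SDF2L1 from 26.2 ± 1.79 to 18.65 ± 1.41 FPKM. Limma camera gave adjusted p = 2.12e-14 for the list.

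**Figure D3:**
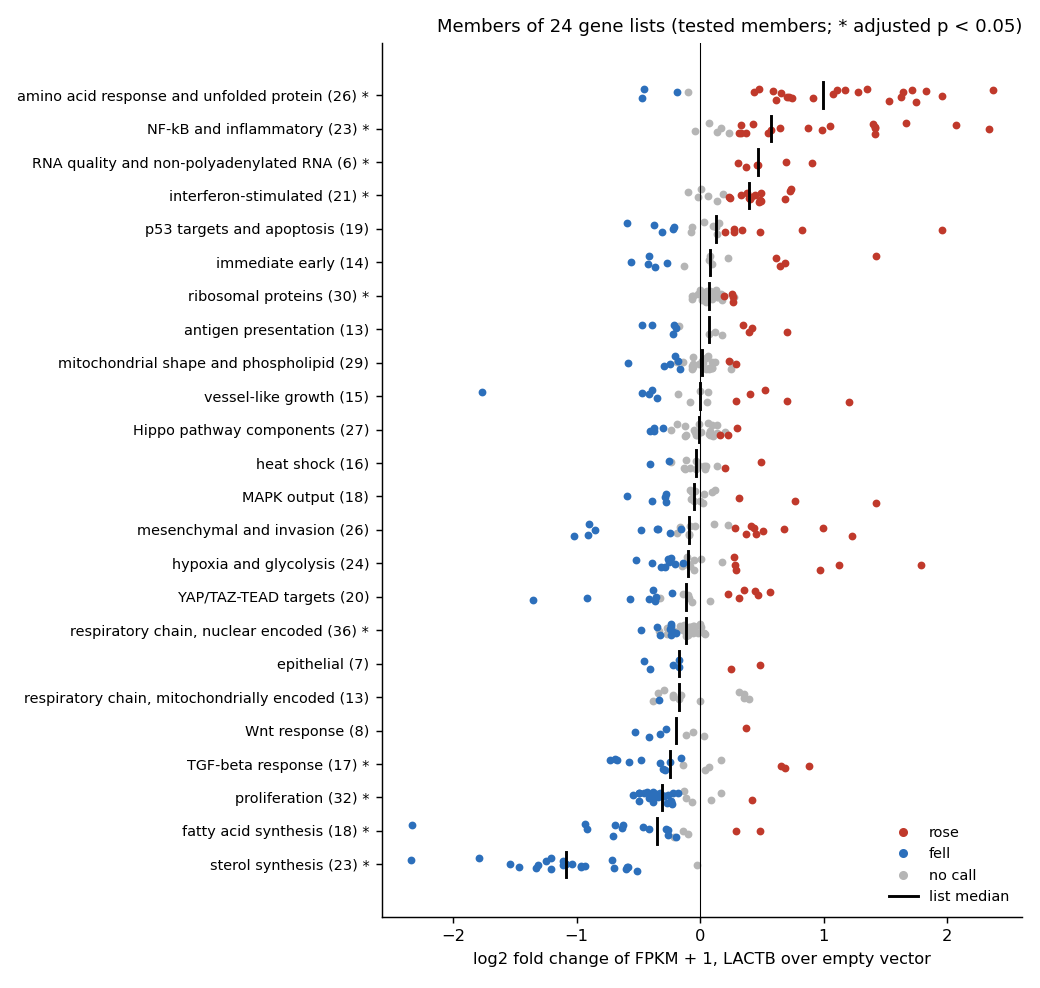
Log2 fold change of FPKM + 1 for the tested members of 24 gene lists, 1 point per gene (red rose, blue fell, grey no call), with the list median as a black bar and the number of tested members in brackets. Lists with an adjusted p under 0.05 in limma camera carry an asterisk; medians run from -1.09 for sterol synthesis to 1.00 for the amino acid response.

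Inflammatory genes rose. In the list of NF-kB and inflammatory genes, 18 of 23 tested members rose and none fell (19 when adjusted over the list alone), with a median log2 fold change of 0.57 (limma camera, adjusted p = 8.87e-14). Besides CXCL1, the cytokine IL1B rose from 11.6 ± 0.358 to 32.5 ± 0.903 FPKM, and IL6, named after its values were seen, from 1.68 ± 0.213 to 6.10 ± 0.674 FPKM. Of 21 tested interferon-stimulated genes, 15 rose and none fell (16 when adjusted over the list alone), with a median of 0.39 (limma camera, adjusted p = 2.17e-07). IFI44 rose from 27.8 ± 1.32 to 46.6 ± 1.95 FPKM and the helicase gene DDX60 from 6.08 ± 0.251 to 8.65 ± 0.196 FPKM. Antigen presentation genes divided, with 4 of 13 up and 5 down (4 and 5 when adjusted over the list alone). HLA-B rose 1.68-fold and the peptide transporter TAP2 1.31-fold, whereas CD274, which encodes PD-L1, fell from 14.0 ± 0.134 to 10.5 ± 0.0712 FPKM and the immunoproteasome subunit PSMB10 was 1.53-fold lower. That list passed no threshold (median 0.07; limma camera, adjusted p = 0.83).

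Proliferation genes were modestly lower. Of 32 tested members, 26 fell and 1 rose (27 and 2 when adjusted over the list alone), with a median log2 fold change of -0.31 (limma camera, adjusted p = 1.48e-08). MKI67, which encodes the Ki-67 antigen, fell from 33.5 ± 1.54 to 23.5 ± 0.954 FPKM, and BIRC5, the mitotic protein survivin, from 62.8 ± 2.28 to 42.9 ± 1.30 FPKM. The exception was CCNE1, cyclin E1, which rose from 1.01 ± 0.166 to 1.68 ± 0.0933 FPKM. Among 19 tested p53 targets, 7 rose and 5 fell (9 and 5 when adjusted over the list alone). The stress sensor SESN2, which the amino acid response list also holds, rose 4.23-fold and the cell cycle inhibitor CDKN1A rose from 7.19 ± 0.729 to 13.45 ± 0.815 FPKM, while CCNG1 and DDB2 were 1.53-fold and 1.36-fold lower. The p53 list passed no threshold (median 0.13; limma camera, adjusted p = 0.162), and passed it with fry (adjusted p = 0.0031) and at a mean FPKM of at least 5 (adjusted p = 0.012) or without a filter (adjusted p = 0.0483); over 20 alternatives it ran from 0.0031 to 0.374.

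Respiratory chain genes encoded in the nucleus moved slightly lower. Of 36 tested members, 9 fell and none rose (7 when adjusted over the list alone), with a median log2 fold change of -0.12. UQCRFS1, the Rieske protein of complex III, fell from 37.3 ± 1.40 to 26.5 ± 0.791 FPKM and ATP5F1A, a subunit of ATP synthase, from 25.95 ± 0.713 to 21.9 ± 0.298 FPKM. Limma camera gave adjusted p = 0.0024, and adjusted p = 0.523 with an estimated correlation, the highest over its alternatives (lowest 8.99e-06). Of the 13 protein genes of the mitochondrial genome, 1 fell (1 when adjusted over the list alone), MT-ATP8, from 687.9 ± 13.75 to 545.6 ± 32.5 FPKM, a call lost without a filter on low values (limma, adjusted p = 0.0557; 0.000155 to 0.0557 over its alternatives). Their list passed no threshold (median -0.17, limma camera, adjusted p = 0.719). Without empty vector replicate 3, the library with the low mitochondrial share, its median was -0.35. Limma camera then gave adjusted p = 0.00231, the lowest over its alternatives (highest 0.995). That value rests on the preset correlation of 0.01, whereas the correlation estimated for these genes over all libraries was 0.866. With the estimated correlation and all libraries, limma camera gave adjusted p = 0.938. Genes of mitochondrial shape and phospholipid synthesis, a pathway in which LACTB has been placed, passed no threshold as a list (median 0.013, mean -0.019; limma camera, adjusted p = 0.936), with 2 of 29 up and 6 down (2 and 6 when adjusted over the list alone). PCYT1A of phosphatidylcholine synthesis and the lipid transfer gene PRELID3B rose 1.246-fold and 1.184-fold, PCYT2 of phosphatidylethanolamine synthesis fell from 4.10 ± 0.210 to 2.41 ± 0.226 FPKM, and IMMT, the cristae organiser, was 1.20-fold lower.

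Genes of cell state and invasion divided. In the mesenchymal and invasion list, 9 of 26 tested members rose and 9 fell (11 and 10 when adjusted over the list alone; median -0.087; limma camera, adjusted p = 0.936). SERPINE2, a protease inhibitor, and TNC, tenascin C, rose 2.56-fold and 2.01-fold, whereas the matrix gene SPARC fell from 135.3 ± 1.45 to 72.2 ± 1.20 FPKM and PLAU, urokinase, from 261.1 ± 11.8 to 128.6 ± 6.70 FPKM. Of 7 tested epithelial genes, 5 fell and 2 rose (5 and 2 when adjusted over the list alone; median -0.17). The keratin KRT7 fell from 158.8 ± 6.85 to 119.9 ± 5.53 FPKM and OCLN, occludin, was 1.59-fold lower, while the claudins CLDN1 and CLDN4 rose 1.19-fold and 1.48-fold. The epithelial list passed no threshold in limma camera (adjusted p = 0.333) and passed it in fry (adjusted p = 0.00174, the lowest over its alternatives; highest 0.834). Vessel-like growth genes, a programme long studied in this cell line, had 5 of 15 up and 5 down (5 and 5 when adjusted over the list alone; median -0.001, mean -0.026, with limma camera's direction upward, adjusted p = 0.86). TFPI2 and the laminin gene LAMB3 rose 2.34-fold and 1.64-fold, whereas CDH5 and THBS1, thrombospondin 1, were 3.57-fold and 1.35-fold lower.

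TGF-beta response genes leaned lower. In that list 10 of 17 tested members fell and 3 rose (10 and 3 when adjusted over the list alone; median -0.25; limma camera, adjusted p = 0.0443, and adjusted p = 0.523 with an estimated correlation, which ended the call). COL4A1, a basement membrane collagen, fell from 15.8 ± 0.166 to 9.56 ± 0.210 FPKM and LTBP2 was 1.77-fold lower, while TGIF1 and BAMBI, inhibitors of the pathway, rose 1.77-fold and 3.51-fold. Other settings that ended this call included the omission of empty vector replicate 1 (adjusted p = 0.0764) or 2 (adjusted p = 0.092), quantile normalization (adjusted p = 0.0565) and eBayes without the variance trend (limma camera, adjusted p = 0.0553); its adjusted p ran from 0.00422 to 0.523 over all alternatives. Of 8 tested Wnt response genes, 4 fell and 1 rose (4 and 1 when adjusted over the list alone; median -0.19; limma camera, adjusted p = 0.204; fry, adjusted p = 0.0289, with 0.0289 to 0.523 over all alternatives), with DKK3 falling from 12.02 ± 0.482 to 8.07 ± 0.764 FPKM.

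Several stress and signalling lists passed no threshold in limma camera although single members changed. Of 24 tested hypoxia and glycolysis genes, 6 rose and 9 fell (6 and 10 when adjusted over the list alone; median -0.10, mean 0.069; adjusted p = 0.593). VEGFA and the glucose transporter SLC2A3 rose 2.79-fold and 2.13-fold, whereas LDHA, lactate dehydrogenase A, fell from 229.9 ± 3.21 to 160.5 ± 4.29 FPKM and the transporter SLC2A1 was 1.33-fold lower. Of 18 tested MAPK output genes, 3 rose and 5 fell (3 and 5 when adjusted over the list alone; median -0.046, mean 0.036; limma camera, adjusted p = 0.83): EGR1 and DUSP4 rose 2.95-fold and 1.82-fold, and ETV1 and SPRY2 were 1.59-fold and 1.33-fold lower. Among 14 immediate early genes, 4 rose and 5 fell (5 and 5 when adjusted over the list alone; median 0.076; limma camera, adjusted p = 0.814), with KLF4 up 1.59-fold and JUN falling from 114.8 ± 4.57 to 77.7 ± 5.83 FPKM. Among 16 heat shock genes, 2 rose and 2 fell (2 and 2 when adjusted over the list alone; median -0.034; limma camera, adjusted p = 0.83), HSPB1 among those that fell, 1.33-fold lower, a call lost without a filter (limma, adjusted p = 0.0538; 0.000338 to 0.0538 over its alternatives).

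Lists that speak to RNA quality and to other cell types were measured beside these. All 6 tested members of the list of RNA quality and non-polyadenylated RNA rose (6 when adjusted over the list alone; median 0.47; limma camera, adjusted p = 0.000316, and adjusted p = 0.157 with an estimated correlation, the highest over its alternatives), with the histone gene HIST1H2AC going from 1.77 ± 0.146 to 4.18 ± 0.139 FPKM and the nuclear long RNA MALAT1 from 25.8 ± 1.68 to 36.1 ± 2.77 FPKM. They moved in the same direction as the amino acid response, inflammatory and interferon lists and against the sterol and proliferation lists. Of 30 ribosomal protein genes, 4 rose and none fell (3 when adjusted over the list alone; median 0.071; limma camera, adjusted p = 0.0116), among them RPS19 at 1.20-fold; without empty vector replicate 2 the adjusted p was 0.134, with fry it was 0.177, and with an estimated correlation it was 0.648 (0.00126 to 0.648 over all alternatives). With an estimated correlation, limma camera kept 6 of the 10 calls: sterol synthesis and NF-kB (adjusted p = 0.0124 each), proliferation (0.0192), fatty acid synthesis and interferon (0.0233 each) and the amino acid response (0.0358). A larger p in this alternative does not by itself show correlated members. The estimated correlation was -0.02 for sterol synthesis and -0.029 for proliferation, below the preset 0.01, and their p-values still rose. Markers of melanocyte identity were nearly absent in both groups: 20 of 22 lay under 1 FPKM, 3 of them with 0 reads, and of the 2 tested, RAB27A fell from 6.002 ± 0.158 to 4.85 ± 0.266 FPKM and RAB38 stood at 10.9 and 12.25 FPKM. The call of RAB27A was lost as TPM (limma, adjusted p = 0.0512; 0.00294 to 0.0512 over its alternatives). Of 15 fibroblast markers 12 lay under 1 FPKM, PDPN fell from 50.5 ± 3.31 to 32.0 ± 0.910 FPKM and FBLN1 was 1.26-fold lower, a call lost without a filter (limma, adjusted p = 0.0554) and as TPM (adjusted p = 0.0584; 0.00247 to 0.0584 over its alternatives). Of 16 leukocyte markers 15 lay under 1 FPKM, and LAPTM5 fell from 33.5 ± 3.09 to 23.3 ± 0.359 FPKM. These 3 lists had fewer than 5 tested members and were not tested as lists.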

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

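The GC and length correction and voom for genes and lists were chosen after seeing the data; all other settings were planned. LACTB stayed higher and past the threshold in all 18 alternatives. The numbers of genes that rose (1758) and fell (2038) stayed within 1.5 times of these in 16 and 17 alternatives. Among the exceptions were 1155 rising at a mean FPKM of at least 5, where fewer genes were tested; 1295 falling as TPM, where 16070 genes were tested and 1615 rose, so that rises made up 55.5% of the calls against 46.3% in the main test; 847 and 1004 at adjusted p under 0.01; and 88 and 48 with a log2 fold change of at least 1 as well. Leaving out 1 library gave 1115 to 1505 rising and 1388 to 1800 falling, with fewer samples. With the replicate number as a replicate block, 1155 rose and 1324 fell, and the TGF-beta list had a camera adjusted p of 0.0584; same-numbered libraries did not deviate together (correlations -0.126, 0.019 and -0.044), so the numbers do not pair the samples, and not every library correlated best with its own number. The median log2 fold change of all genes stayed between -0.022 and 0.014. At these depths and with 3 libraries a group, the simulated test called 46.9% of 1.25-fold changes, so changes of that size can be missed. That share came from data with few changed genes and a stricter cutoff, so it does not give the sensitivity of the real test. Genes called in the real data had a median absolute log2 fold change of 0.31.

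Of 10 called lists, 5 higher and 5 lower, camera with an estimated correlation kept 3 and 3, and fry called 8 lower. The YAP and TAZ target list (median -0.116) passed the threshold only with fry. The direction given by the list test turned 22 times, always for lists that passed no threshold in the main test; the median changed sign in 4 of these and did not in 18. The cause was not tested. Where camera's direction turned without a filter, medians were -0.004 for the mesenchymal and -0.005 for the antigen presentation list. As TPM they were -0.059 for the mesenchymal, 0.049 for the mitochondrial shape and -0.004 for the vessel-like list. The mitochondrial shape list had 0.018 at a mean FPKM of at least 5, 0.022 after quantile normalization and 0.027 with library weights. The Hippo list had 0 after quantile normalization and 0.02 after GC and length correction. Fry gave an upward direction where camera's was downward for the mesenchymal (-0.087), hypoxia (-0.101) and MAPK (-0.046) lists, with the medians of the main test. Over the libraries left out in turn, camera's direction turned at least once for 7 lists, whose medians ran from -0.012 to 0.02 for the Hippo list, -0.095 to -0.069 for the mesenchymal, -0.351 to -0.054 for the mitochondrially encoded, -0.052 to -0.02 for the MAPK, -0.029 to 0.053 for the mitochondrial shape, -0.03 to 0.037 for the vessel-like and -0.078 to 0.131 for the immediate early list, and the log2 fold change of PPP1CA from -0.086 to 0.009. For named genes, 1728 values kept side and direction, 63 lost their call, most of them for MIR125B1, STK3, ACSS2, LEF1, SP5, HSPA1A, HSPA1B and BAG3, and 3 gained one, all for YAP1.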

Other observations

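The lists in this part, the tests that use them, the copy number test and the GC and length correction were chosen after the main gene results, and medians by chromosome, had been seen. Targets of NRF2, the transcription factor of the oxidative stress response, rose: 14 of 18 tested members rose and none fell, with a median log2 fold change of 0.43 (limma camera, adjusted p = 2.03e-08, and adjusted p = 0.0785 with an estimated correlation). The quinone reductase NQO1 rose from 64.0 ± 0.883 to 162.8 ± 3.30 FPKM and thioredoxin reductase TXNRD1 from 171.9 ± 3.47 to 306.8 ± 2.12 FPKM. The ferritin light chain gene FTL rose from 1228 ± 143.8 to 3224 ± 137.2 FPKM; its many pseudogenes can share its reads. Of 19 tested cytosolic tRNA synthetase genes, 11 rose and 1 fell, with a median of 0.42 (limma camera, adjusted p = 3.86e-06, and adjusted p = 0.0321 with an estimated correlation). GARS rose from 113.3 to 207.5 FPKM and MARS from 22.4 to 43.1 FPKM, while KARS stood at 62.35 and 62.3 FPKM. Of 16 tested mitochondrial tRNA synthetase genes, 2 rose and 2 fell, with a median of 0.053 (limma camera, adjusted p = 0.188). The mitochondrial list holds no counterpart of GARS or KARS, so the lists do not cover the same set of enzymes. The difference between both lists was not tested.

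In a line that the labels call melanoma, the melanocyte genes MLANA, PMEL and SOX10 stood at 0.121, 0.2 and 0.0151 FPKM in the empty vector libraries, and MITF at 0.657 FPKM. Only 7 of the 19 genes of the epithelial list reached a mean of 1 FPKM over the 6 libraries. Of this list, the keratins KRT7, KRT8 and KRT18 stood at 158.8, 184.9 and 161.8 FPKM in the empty vector libraries, whereas CDH1, EPCAM and KRT19 stood at 0.00299, 0.236 and 0.279 FPKM, and GRHL2 and RAB25 had 0 reads. In the same libraries the mesenchymal gene VIM stood at 511.6 FPKM, and CDH5, of the vessel-like growth list, at 49.8 FPKM. Of the 24 genes of that list, 15 reached a mean of 1 FPKM over the 6 libraries. The identity of the line was not tested, and these values do not settle it.

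Between LACTB and empty vector, 3796 of 11875 tested genes passed the threshold. With 6 libraries there are only 10 splits into 3 and 3, too few for a share under 0.05: 1 split, the real one, gave that many, and the highest of the others gave 0. A difference in chromosome copy number between the 2 cell populations would move runs of neighbouring genes together, and 0% of the genes that changed lay in windows of 50 neighbouring genes with a median beyond 0.25; over 226 windows the largest absolute median was 0.192, just above the 0.183 that was highest among 100 shuffles, so small regional shifts stay open. Without empty vector replicate 3, which had the low mitochondrial share, 3305 genes passed the threshold, 3024 of them shared with the full comparison, which argues against that library as the source. Differences in density, medium or harvest between cultures, and chance differences between the cell populations that received each vector, were not tested and may contribute.

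The fall of sterol synthesis genes was not explained by GC content or gene length: after removal of both trends the list median was -1.08. An excess of sterol is a candidate explanation, since it shuts off these genes, and sterol derivatives also raise targets of the receptor LXR; 0 of the 2 tested LXR targets rose, and both fell (median -0.476; ABCA1 from 3.59 to 2.26 FPKM and MYLIP from 3.39 to 2.195 FPKM). This argues against sterol excess acting through LXR, on 2 genes only. It cannot decide on an excess of sterol that shuts off the synthesis genes without raising LXR targets. Other routes to lower activity of the sterol-regulated transcription factors, a direct effect of LACTB and a difference in serum or cell density may account for the fall and were not tested.

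The rise of amino acid response genes was weighed against 2 kinds of protein folding stress. The median log2 fold change of 11 endoplasmic reticulum chaperones and folding factors was -0.368, with 8 falling and 2 rising (limma camera, adjusted p = 0.0114, and adjusted p = 0.0785 with an estimated correlation). The amino acid response list holds 6 of these 11, some of whose values had been seen. The other 5 (HSP90B1, DNAJC3, CRELD2, MANF and PDIA6) all fell, with a median of -0.378. What would count for or against this stress was written down after values had been seen, so these falls are no independent test of it. Their direction is opposite to that of a general folding stress of that compartment, although XBP1, HERPUD1 and DNAJB9 rose. For 13 mitochondrial chaperones and proteases the median was 0.043, with 3 rising (HSPA9, LONP1 and DNAJA3) and none falling (limma camera, adjusted p = 0.127), so stress of mitochondrial protein folding cannot be told apart from other inputs: members near 0 decide neither way. The median of 0.434 for NRF2 targets, tested without AKR1C1, NMRAL2P and SLC7A11, is consistent with raised NRF2 activity as a hypothesis for the rise of those genes, and its list call was lost with an estimated correlation. A shortage of amino acids in denser cultures may give the same response and was not tested.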
